A study of Mus musculus with 6 samples.

How the data were processed

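Mouse embryonic fibroblasts (MEFs), connective tissue cells cultured from embryos, were left untreated or treated with interferon-beta (IFN-beta), a type I interferon that cells secrete on viral infection. Per the labels, the dose was 2500 units per ml for 5 h, total RNA was taken from 3 biological replicates per group, and about 10 µg of it was turned into biotin-labelled cRNA. Each of the 6 samples was read on 1 single-colour oligonucleotide array. Groups and replicate numbers were taken from the sample titles. The extraction text of untreated samples 2 and 3 names both conditions, so it was not used to assign a group.

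The authors deposited 1 signal intensity per probe set and array on a linear scale, and the submitters' processing notes name MAS5, Affymetrix's method that combines the probes of a set into 1 value. The MAS5 version and the detection calls are not given in the sources used here. The 2%-trimmed mean of the deposited values was 250.1 or 250.2 on each array, as checked on the values, so the arrays had already been brought to 1 scale and were not rescaled. Such scaling removes any difference in total RNA between groups, and a fold change is therefore relative to the bulk of the transcripts. The values have no read depth, and the number of arrays limits the precision.

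The table held 12488 probe sets. The 66 control sets were kept out of the tests, leaving 12422. The platform annotation supplied with the series gave 1 gene symbol for 10833 of these, several genes for 396 and none for 1193. Of the 10833, 10817 were matched by Entrez number to NCBI RefSeq genes of the GRCm38.p6 assembly, with 0 symbols changed by the match. That assembly was used only for names and for the order of neighbouring genes, since no build is named for the array. Probe sets with several genes or none were left out of the gene-level test and were examined on their own. For the 2073 genes with several probe sets, the set with the highest mean log2 value was used. This choice was blind to group, but it can pick a probe set that responds less than another, as the text states for Irf7. Suffixed probe sets are those whose identifier marks shared sequence or a relaxed choice of probes. A gene without a value here was not analysed here.

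Signals were converted to log2(signal + 13.8), where 13.8 was the 20th percentile of all values. Fold changes are on this scale and understate the change of dim genes. A gene was tested if its signal exceeded 49.6, the 40th percentile, on at least 3 of the 6 arrays, whichever they were, which kept 5716 of 8251 genes. The groups were compared with a linear model in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend and robust variances, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Values are means ± SD of the signal over 3 arrays, and SE is the standard error of the log2 fold change. Unless another fit is named, each adjusted p comes from this limma model.

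The titles give both groups the same replicate numbers, 1 to 3, and nothing in the labels says what a number stands for. Each array's deviations from its group mean were correlated across genes. The same-numbered arrays correlated at 0.82, 0.74 and 0.70 for numbers 1, 2 and 3, and the other pairs across groups at -0.51 to -0.12. By a rule fixed before the data were examined, all 3 values above 0.1 meant that the numbers paired the samples. The pairing thus comes from the data and the shared numbers. The group comparison without the number stayed the primary one, as fixed beforehand. Values from the same model with the replicate number as a block are called blocked and stand beside many of the results that they alter. SEs are from the model without the block unless blocked is named. They then include the spread between replicate numbers and can hide small changes that the pairs share. No 2 arrays held identical values, and correlations across genes between arrays of 1 group ran from 0.89 to 0.93.

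The text names genes by a rule written before the data were examined. It took the 12 largest rises and the 8 largest falls past the threshold with no overlap between groups and a signal above the pooled median of 86.6. From each gene list it took the 4 members with the largest change past the threshold, or 2 members where none passed. These 2 were not always the members with the largest fold change. In the complement, leukocyte, endothelial, muscle and neural, and ribosomal lists, members with larger fold changes than a named one were not named. The rule also took a few fixed genes, among them Ifnar1, Ifnar2, Stat2, Irf9 and Irf7, whatever their values. Last, it took genes with 2 probe sets past the threshold in opposite directions, of which there were 0. Genes named outside this rule were chosen after their values were seen. They include Igf2bp1, Rps6kb2, Rps6kc1, Ndufaf1, Ndufaf4, Hspa1b, the genes named in the closing section, Nmi, Irf5, Jak2, Ccl2, Il6, Dusp1 and S100a4, past the threshold in the blocked model alone, and the genes that fell in it. Stat2 was not analysed here, and 1 item of the rule is not reported here.

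A set of 23 gene lists was likewise fixed beforehand. They covered antiviral effectors, interferon-inducible GTPases, the HIN-200 family, MHC class I and antigen processing, interferon signalling, pattern recognition, ISGylation, and chemokines and cytokines. Others covered NF-kappaB targets, complement, cell death, the cell cycle, sterol synthesis, fibroblast and matrix genes, immediate early genes, heat shock and the unfolded protein response. The rest held markers of leukocytes, endothelium, epithelium, muscle and nerve, ribosomal proteins, oxidative phosphorylation and reference genes. Some genes stand on 2 lists. Symbols were also matched through synonyms, and by this Igf2bp1 was wrongly taken for Zbp1 on the antiviral list, since both genes have carried that name. The name patterns also took 2 S6 kinases onto the ribosomal list and 2 complex I assembly factors, Ndufaf1 and Ndufaf4, onto the oxidative phosphorylation list. All were kept in the list tests except those that name their removal. The 22 lists with at least 4 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, by camera with an estimated correlation, and by fry, which asks whether a list's genes moved 1 way without comparing them with others. P-values were adjusted over the lists. Members past the threshold were also counted after adjustment over the list alone, without the block unless blocked is named.

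The gene test was tested on simulated arrays with 200 of 5716 genes changed, in 10 draws. It recovered 32.8% of genes changed by 1 log2 unit, 77.2% at 2 and 95.5% at 4, and 0.51% of calls were false. The blocked model recovered 62.8%, 87.8% and 98.3%, with 2.76% of calls false. Both camera tests found all 10 planted lists and called 0 of 30 lists without a planted change. Of these 30, fry called 0, and 1 in the blocked model. The simulated genes varied independently of one another and the lists held random genes. Every member of a planted list was raised, by 1, 2 or 4 log2 units, and lists were called at an unadjusted p under 0.05. These draws therefore could not show how the list tests, above all camera with the preset correlation, behave where genes vary together. Nor could they show how the tests behave where few members change or the changes are small. Alternatives covered the offset, the filter, the scaling between arrays, the choice of probe set, the variance model, array weights, the replicate block and the omission of each array. Combinations of the block with these, the omission of a same-numbered pair, the stricter matching of synonyms and the removal of members taken in by name were chosen after seeing the data.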

Results

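The series asked which transcripts respond to IFN-beta in MEFs. It held 3 untreated arrays and 3 arrays from cells given 2500 units per ml of IFN-beta for 5 h. The median signal was 85.9 to 90.8 on the untreated arrays and 83.7 to 85.3 on the IFN-beta arrays. In each array 59.0% to 61.7% of probe sets exceeded the filter of 49.6.

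IFN-beta raised the transcripts of many interferon-stimulated genes. Ifit1, which binds viral RNA, went from a signal of 12.4 ± 9.4 to 6061 ± 1104 (SD, n = 3 per group), a log2 fold change of 7.90 ± 0.29 (SE) on the log2(signal + 13.8) scale, with a limma adjusted p of 1.70e-05. Usp18, which removes ISG15 from proteins and dampens interferon signalling, rose from 6.47 ± 6.07 to 2670 ± 447, a log2 fold change of 7.08 ± 0.27. Ifit3 rose by 6.90 ± 0.25, the chemokine Cxcl10 by 6.88 ± 0.33 and the guanylate-binding GTPase Gbp2 by 6.79 ± 0.35 on the log2 scale. Next came Iigp1 (6.20 ± 0.63), the antiviral GTPase Mx1 (5.72 ± 0.55), Gbp3 (5.58 ± 0.52), the ubiquitin-like modifier Isg15 (5.48 ± 0.31), Igtp (5.34 ± 0.27), Ifi47 (5.07 ± 0.46) and Gm9706 (5.00 ± 0.37). This order depends on the offset of 13.8, since some of these genes had lower untreated signals than that. Gm9706 is annotated as a pseudogene, and its probe set carries a suffix used for probes shared between related sequences. Each of these 12 genes was higher in IFN-beta than in untreated cells in 3 of 3 same-numbered pairs, which the naming rule ensured by asking for no overlap between groups.

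**Figure D1:**
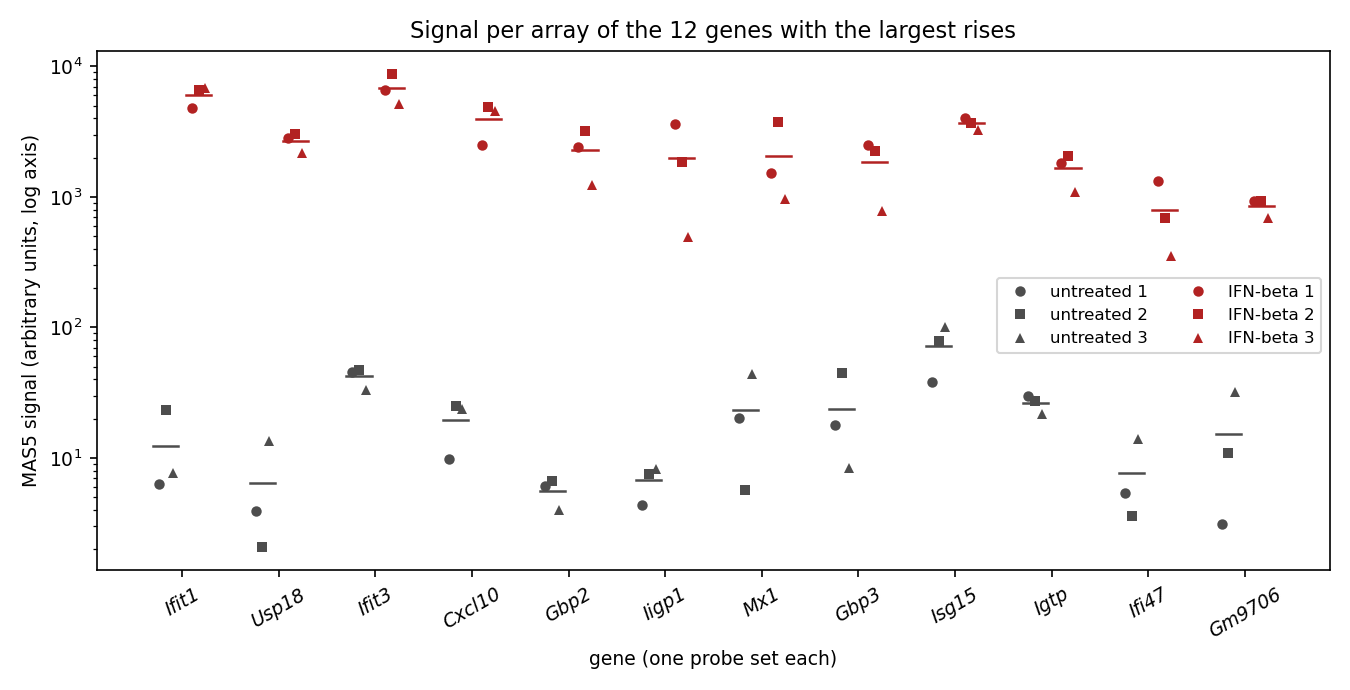
MAS5 signal in arbitrary units on a log axis for the 12 genes with the largest rises, with 1 point per array (circle, square and triangle for replicates 1, 2 and 3) and a line at each group's mean of 3 arrays. In every gene the IFN-beta arrays lie above the untreated ones, as the rule that chose the genes required, for Ifit1 at a mean of 6061 against 12.4.

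Across 5716 genes, 56 rose and 0 fell, all 56 by at least 2-fold, with a median log2 fold change of 2.96 and a range of 1.38 to 7.90. At an unadjusted limma p under 0.05, 162 genes were higher and 39 lower, and 423 and 633 in the blocked model. The IFN-beta and untreated arrays did not overlap in 484 genes, 209 higher and 275 lower with IFN-beta. That is 8.47% of the genes. Chance would give 10% for 3 arrays against 3 only if all arrays varied independently of one another. Same-numbered arrays deviated together, and the comparison parts each such pair, so the 10% does not apply here. Whether more or fewer genes were separated than by chance is therefore left undecided. The blocked model gave 171 genes higher, among them all 56, and 40 lower. With each array centred on its median, the blocked counts were 196 and 17. Without IFN-beta replicate 2, 37 genes rose in the model without the block, and no other single array moved the 56 by over 1.5 times.

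Antiviral effectors rose in part. Of 23 tested members, 12 rose, 0 fell and 11 did not pass, 3 of them with fold changes below 0. Adjusted over the list alone 17 rose, and 16 rose in the blocked model. One of those below 0, Igf2bp1, was put on the list by a wrong synonym match, and without it 12 of 22 rose. Ifit1 and Ifit3 led, followed by Mx1, which went from 23.3 ± 19.3 to 2074 ± 1458, and Isg15, from 72.3 ± 31.7 to 3652 ± 397 (SD, n = 3). The list's camera adjusted p was 3.80e-53, and adjusted p = 0.00427 with an estimated correlation. All 8 tested interferon-inducible GTPases rose, also 8 adjusted over the list alone, by log2 fold changes of 3.48 to 6.79. These proteins act on vacuoles that hold intracellular microbes. Gbp2 went from 5.6 ± 1.4 to 2290 ± 988 and Igtp from 26.3 ± 4.0 to 1655 ± 499. The GTPase list had an adjusted p of 5.93e-47, and adjusted p = 0.0193 with an estimated correlation. All 3 tested HIN-200 genes, which encode nuclear and DNA-binding proteins, also rose, 3 adjusted over the list alone. Here the list named 13, of which 4 had a probe set of their own. They were Ifi202b (log2 fold change 4.11 ± 0.40), Ifi204 (3.79 ± 0.47) and Ifi207 (3.15 ± 0.51), and the probe sets of Ifi204 and Ifi207 are of the shared-sequence kind. With under 4 members, the HIN-200 list had no set test, and the adjusted p of Ifi207 lay between 0.0103 and 0.151 with 1 array left out, past the threshold only without untreated replicate 1.

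MHC class I and antigen-processing genes rose in part. Of 13 tested, 7 rose and 0 fell, or 9 adjusted over the list alone, and 9 rose in the blocked model. The immunoproteasome subunit Psmb8 had a log2 fold change of 3.74 ± 0.54, the peptide transporter Tap1 of 3.16 ± 0.43, the class I heavy chain H2-K1 of 2.88 ± 0.30 and Psmb10 of 2.52 ± 0.36. H2-K1 was read by a shared-sequence probe set. A second such set gave 3.03, and the unshared one gave -0.07, at signals of 87.9 and 86.5. A second probe set of Tap1 went from 63.7 to 40.6, a log2 fold change of -0.52 with an adjusted p of 0.999 among all probe sets. The list's adjusted p was 6.40e-27, and adjusted p = 0.0219 with an estimated correlation. The count of 7 fell to 4 without untreated replicate 1 or IFN-beta replicate 1, to 2 without untreated replicate 2, and to 1 without untreated replicate 3 or IFN-beta replicate 2. With 1 array left out, the highest adjusted p was 0.109 for Psmb8 (without IFN-beta replicate 2), and without untreated replicate 3 it was 0.0714 for Tap1, 0.0925 for Psmb10 and 0.0293 for H2-K1.

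Among interferon signalling components, 4 regulators rose and the receptor chains had fold changes near 0 by their brightest probe sets. The log2 fold changes of Ifnar1 and Ifnar2, the 2 chains of the IFN-beta receptor, were 0.03 ± 0.41 and 0.01 ± 0.23 (adjusted p 0.999 for both). A second probe set of Ifnar2 gave 0.37, with an adjusted p of 0.999 among all probe sets. Of 25 tested members, 4 rose and 0 fell, or 6 adjusted over the list alone. Besides Usp18 they were Socs1, a feedback inhibitor of JAK kinases, from 89.5 ± 3.9 to 761 ± 139, Irf9, the DNA-binding subunit of the complex ISGF3, from 112 ± 26 to 855 ± 27, and Irf1, from 153 ± 17 to 907 ± 276 (SD, n = 3). The blocked model gave 8 higher, adding Nmi, Irf5, Jak2 and Irf7. Irf7, a transcription factor of the interferon genes, had a log2 fold change of 0.73 ± 0.26 by its brightest probe set, with an adjusted p of 0.964 and of 0.0255 when blocked. Its second probe set went from 17.6 to 451, a log2 fold change of 3.73 with an adjusted p of 0.00395 among all probe sets. The list's adjusted p was 9.89e-13, and adjusted p = 0.0134 with an estimated correlation.

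Of 6 pattern-recognition genes, 2 rose, 2 adjusted over the list alone, and 3 rose in the blocked model. They were Ifih1, a cytoplasmic sensor of double-stranded RNA (log2 fold change 4.45 ± 0.40), and the adaptor Myd88 (1.51 ± 0.21). The adjusted p of Myd88 lay between 0.0272 and 0.0925 with 1 array left out, past the threshold only without IFN-beta replicate 3, so that 1 gene rose in each of the other 5 omissions. The list's adjusted p was 6.01e-05, and adjusted p = 0.0445 with an estimated correlation. On the ISGylation and ubiquitin list 4 of 6 members rose, 4 adjusted over the list alone. Beside Isg15 and Usp18 these were the conjugating enzyme Ube2l6 (2.88 ± 0.33) and the activating enzyme Uba7 (2.32 ± 0.31), the latter at an adjusted p of 0.0659 without IFN-beta replicate 2 and under the threshold in all other omissions but that of untreated replicate 2. Its adjusted p as a list was 6.18e-19, and adjusted p = 0.0219 with an estimated correlation. In the blocked model the camera adjusted p with an estimated correlation was 0.197 for each of the antiviral, GTPase, MHC, signalling, pattern-recognition and ISGylation lists, while blocked fry gave 0.00769 to 0.03. The block leaves few degrees of freedom, on which that camera test rests, so a miss in it says little. The GTPase list had an unadjusted camera p of 0.0472 there, although all 8 members rose when blocked. Other splits of the 6 arrays into 3 and 3 put up to 10 lists past camera with the preset correlation, and 0 with the estimated one.

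**Figure D2:**
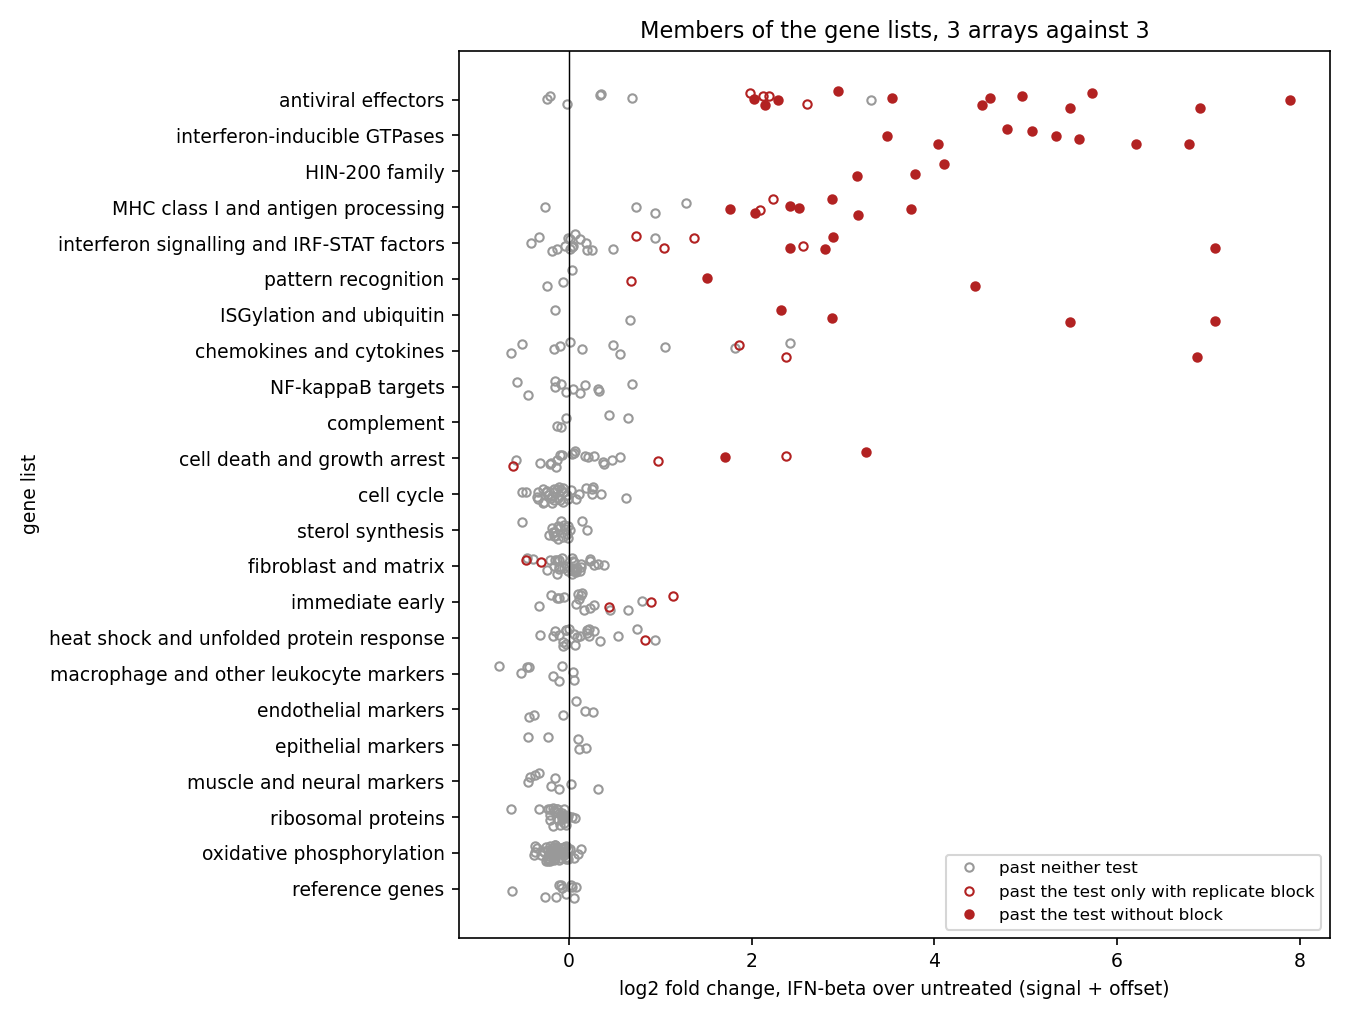
Log2 fold change of IFN-beta over untreated cells, on the log2(signal + 13.8) scale, for each tested member of the 23 gene lists. Filled red points passed the limma test without the replicate block, open red points passed only with it, and grey points passed neither. The 8 GTPases lie between 3.48 and 6.79, and oxidative phosphorylation genes lie between -0.39 and 0.13.

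Chemokines and cytokines gave 1 riser among 14 tested of 36 on the array, Cxcl10, or 3 adjusted over the list alone. The blocked model gave 3, adding the monocyte chemoattractant Ccl2 and the cytokine Il6. Blocked and adjusted over the list alone, 7 rose and 2 fell. Ccl2 differed widely between replicate numbers, and its log2 fold change was 2.37 with an adjusted p of 0.999, and of 1.31e-04 when blocked. Of 23 cell death and growth arrest genes 2 rose, 3 adjusted over the list alone, and 4 rose and 1 fell in the blocked model. The risers were Daxx (log2 fold change 3.25 ± 0.22) and Pml (1.71 ± 0.22), which encode proteins of PML nuclear bodies. Pml had an adjusted p of up to 0.0555 with 1 array left out, and it missed the threshold, leaving 1 riser, without untreated replicate 2 or 3 or IFN-beta replicate 2. For chemokines and cytokines the camera adjusted p was 6.32e-07, but adjusted p = 0.132 with an estimated correlation. For cell death it was 3.63e-05, but adjusted p = 0.125 with an estimated correlation.

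Of 19 immediate early genes, which respond early to many stimuli, 0 rose, 0 adjusted over the list alone and 4 at an unadjusted limma p under 0.05. Zfp36, which destabilises messenger RNA, had a log2 fold change of 1.13 ± 0.37 and Klf4 of 0.90 ± 0.26. Both passed when blocked (adjusted p 0.0336 and 0.00446), as did Dusp1. Of 24 heat shock and unfolded protein response genes 0 rose, 0 adjusted over the list alone and 2 unadjusted, Trib3 (0.83 ± 0.30) and, named after its value was seen, Hspa1b (0.74 ± 0.29). Trib3 passed when blocked (adjusted p 0.0107), and Hmox1, which did not pass unadjusted, was at 0.94 ± 0.50. The camera adjusted p was 3.64e-04 for immediate early genes, upward, but adjusted p = 0.125 with an estimated correlation. For heat shock it was 0.0159, upward, but adjusted p = 0.125 with an estimated correlation, and 0.134 without IFN-beta replicate 2, 0.113 without untreated replicate 1 and 0.0639 without untreated replicate 3.

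Oxidative phosphorylation genes had small negative fold changes. Of 62 tested, 58 lay below 0, the median log2 fold change was -0.16, and 0 fell by limma, 0 adjusted over the list alone and 0 unadjusted. Ndufab1 and Ndufb9, both subunits of complex I, were at -0.39 ± 0.44 and -0.38 ± 0.24. Their blocked SEs were 0.113 and 0.146, with blocked adjusted p of 0.124 and 0.229. The camera adjusted p was 0.0151, downward, but adjusted p = 0.729 with an estimated correlation. It was 0.915 without IFN-beta replicate 2, 0.239 without untreated replicate 3 and 0.092 without untreated replicate 1. Ribosomal protein genes lay below 0 in 26 of 28 cases with a median of -0.11, which was -0.03 after quantile normalization and -0.06 after median centring, and 0 fell, 0 adjusted over the list alone and 0 unadjusted. The 28 include Rps6kb2 and Rps6kc1, kinases that the list's name pattern took in wrongly, and without them 24 of 26 lay below 0. Rpl13a was at -0.23 ± 0.47 and Rpl19 at -0.21 ± 0.27. Their blocked SEs were 0.094 and 0.055, with blocked adjusted p of 0.244 and 0.0882. In the blocked model 0 members fell over all genes, and 3 fell adjusted over the list alone. The ribosomal list's adjusted p was 0.379, and 0.0122 without untreated replicate 2. In the blocked model it was 0.00665, but adjusted p = 0.244 with an estimated correlation, and it was 0.711 when blocked after quantile normalization and 0.113 after median centring. The median of all 5716 genes was -0.08. The Gapdh 3'/5' signal ratio, a sign of RNA quality, was 1.35 ± 0.30 untreated and 1.14 ± 0.27 with IFN-beta (SD, n = 3) and lower in 3 of 3 pairs.

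Without the block, no member of the other lists passed by limma, whether over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there was 1, the fibroblast list's Col5a1, which was lower. Blocked and adjusted over the list alone, 1 NF-kappaB target rose, and 3 fibroblast genes and 1 reference gene fell. In the 12 NF-kappaB targets, Ptgs2 was at 0.68 ± 0.37 and Relb at -0.57 ± 0.33. Complement (5 genes) included C1ra at 0.44 ± 0.57 (1.31 by a second probe set) and Cd59a at -0.03 ± 0.29. That list's median changed sign between scalings, from -0.03 to 0.02 with median centring. The 37 cell cycle genes had a median of -0.14, with Ccnd2 at 0.62 ± 0.33 and Ccne1 at -0.51 ± 0.30, and the 20 sterol synthesis genes one of -0.09, with Dhcr7 at -0.52 ± 0.45 and Mvd at -0.22 ± 0.29. The camera adjusted p of these 4 lists ranged from 0.379 to 0.788. The cell cycle list reached 0.032, downward, without untreated replicate 2, and 0.0345 by blocked fry, but adjusted p = 0.954 with an estimated correlation and 0.362 when blocked with it. The sterol list reached 0.0216 without untreated replicate 3 and 0.0168 without IFN-beta replicate 1, but with all arrays adjusted p = 0.954 with an estimated correlation.

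Lists of markers of fibroblasts and of other cells that such cultures can hold did not pass camera with all 6 arrays, but the muscle and neural list was lower by blocked fry (adjusted p 0.0345, but adjusted p = 0.503 with an estimated correlation in the blocked model). The 35 fibroblast and matrix genes had a median of 0.00, with Col5a1 at -0.47 ± 0.20 and Pdgfra at -0.46 ± 1.39, and 2 of them, Col5a1 and S100a4, fell in the blocked model (adjusted p 0.0232 and 0.0274). Other tested probe sets of Col5a1 and Pdgfra gave 0.07 and 0.26. The 9 leukocyte markers had a median of -0.17, with Laptm5 at -0.44 ± 0.27 and Csf1r at -0.17 ± 0.63, and the list's adjusted p of 0.235 became 0.0387, downward, without untreated replicate 1, but with all arrays adjusted p = 0.547 with an estimated correlation. Endothelial Eng and Flt1 were at -0.38 ± 0.28 and 0.08 ± 0.24, epithelial Krt19 and Muc1 at -0.45 ± 0.37 and -0.23 ± 0.32, and Myod1 and Tubb3 of the muscle and neural list at -0.20 ± 0.21 and -0.15 ± 0.31. The camera adjusted p was 0.869 for fibroblast genes, 0.995 for endothelial and for epithelial markers, and 0.486 for muscle and neural markers. The epithelial median was 0.10 and its mean -0.06, and the means of the fibroblast, endothelial and complement lists (-0.02, -0.06 and 0.17) likewise differed in sign from their medians. Reference genes (11 tested) gave 0.788, with Actb at -0.62 ± 0.48 and Tubb5 at -0.26 ± 0.25. Their blocked SEs were 0.211 and 0.062, with blocked adjusted p of 0.222 and 0.0653. Second probe sets of Actb and Tubb5 gave -0.21 and -0.09.

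In the blocked model 40 genes fell, by a median log2 fold change of -0.57, from -1.25 to -0.31, each in 3 of 3 pairs. That each pair was lower follows largely from passing that model and adds no support. Chosen after their values were seen by the rule for falls, these included Ten1, a telomere-capping subunit (-1.25 ± 0.23, blocked adjusted p 0.0202), the immune ligand Cd70 (-1.20 ± 0.22, 0.0206), the cholesterol exporter Abcg1 (-1.09 ± 0.21, 0.0264) and the serotonin receptor gene Htr1d (-0.96 ± 0.16, 0.0139). Asl (-0.94 ± 0.20), Midn (-0.66 ± 0.11), Fbxo45 (-0.63 ± 0.14) and the survival factor gene Bcl2l1 (-0.62 ± 0.12) followed. Asl was read by a suffixed probe set, and its unsuffixed one, too dim to be tested, went from 29.0 to 27.6. Without the block their adjusted p lay between 0.112 and 0.999. The number that fell in the blocked model was 26, 53 and 23 with pair 1, 2 or 3 left out, among them 15, 21 and 12 of the 40. It was 43 after quantile normalization, with 37 of the 40 kept, 17 after median centring, 6 with no filter, and 7, of which 4 were among the 40, without the intensity trend and robust variances.

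The arrays were arranged first by replicate number. The first principal component, with 41.0% of the variance, set both arrays of number 1 at -33.5 and -30.1 apart from the 4 others at 13.4 to 19.3. The 3'/5' signal ratio of Actb, which rises as RNA is degraded, was 1.65, 1.75 and 2.59 on untreated arrays 1 to 3 and 1.49, 1.72 and 2.66 on the IFN-beta arrays, so number 3 stood apart in both groups (exact permutation p of the group difference 0.9, two-sided, where 0.1 is the smallest possible). The Gapdh 3'/5' ratio was lower with IFN-beta in each pair, at 1.19, 1.16 and 1.70 against 1.00, 0.97 and 1.45 (exact permutation p 0.5), in the same arrays in which the oxidative phosphorylation list and the 40 genes above were lower.

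**Figure D3:**
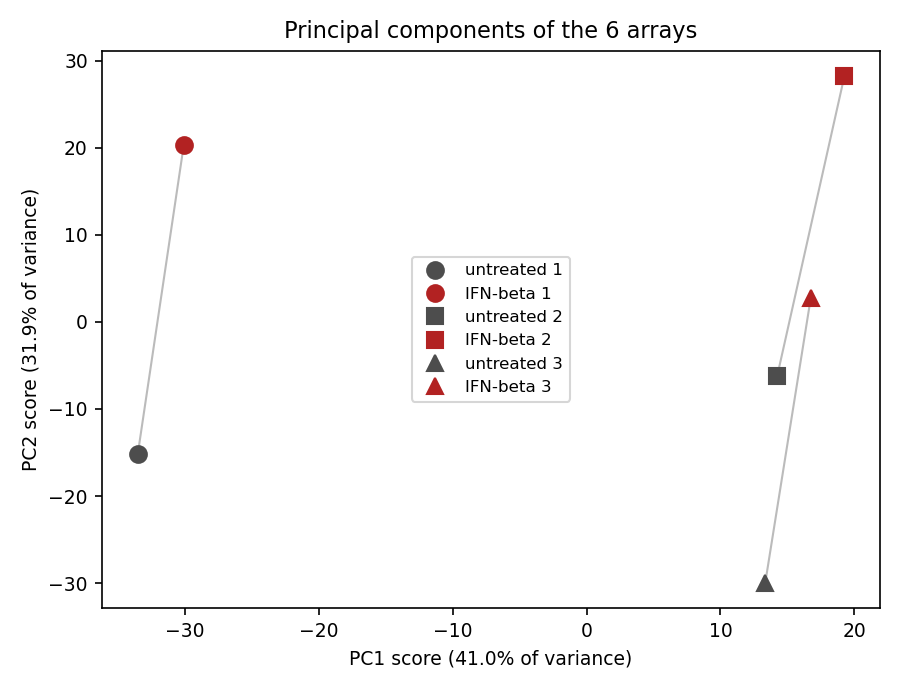
Scores of the 6 arrays on the first and second principal components of the log2 values of all tested genes, with a grey line joining same-numbered arrays. Number 1 lies apart on the first component (41.0% of the variance), and each IFN-beta array lies above the untreated array of its number on the second (31.9%).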

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

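The tests of shared array processing, of between-array scaling and of a single array were chosen after the results they bear on were seen.

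Probe sets kept out of the gene comparison also responded. Among 508 such sets with no gene in the annotation, 1 rose with IFN-beta, from a signal of 28.4 ± 8.1 to 1110 ± 361 (SD, n = 3 per group; log2 fold change 4.70, limma adjusted p 2.89e-04). Among 257 with several genes, 5 rose and 0 fell. These were a set shared by Tgtp1 and Tgtp2 (log2 fold change 7.57), one shared by Ifi203 and related genes (5.59), one shared by Mndal, Ifi211, Ifi205 and Ifi204 (4.76), and 2 shared by H2-T9, H2-T22 and H2-T10 (2.78 and 2.65).

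The same-numbered arrays deviated together, at correlations of 0.82, 0.74 and 0.70. RNA degradation confined to number 3, the one with the high Actb ratio, is argued against as the whole source. With number 3 left out, the difference between numbers 1 and 2 still correlated at 0.811 across genes between the groups. This is silent on number 3 itself. The Actb ratio was slightly higher in number 2 than in number 1 in both groups (1.75 and 1.65 untreated, 1.72 and 1.49 with IFN-beta), and the Gapdh ratio slightly lower. Degradation as a part of the source was thus not excluded. Shared array processing stays open, since spike-in transcripts added to the hybridisation, which do not come from the cells, differed least within numbers, rank 1 of 6 possible matches (mean log2 difference 0.136 against 0.267 to 0.545). RNA levels that differed between separate cell preparations stay open too, since 2 different probe sets of 1 gene gave like differences between numbers 1 and 2 (r = 0.659 across 495 genes, which are not independent replicates).

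The 40 genes that fell in the blocked model had a median log2 fold change of -0.572. It was -0.578 after quantile normalization and -0.518 after median centring, which argues against between-array scaling as the whole source of the fold. After quantile normalization 37 stayed past the threshold (95% binomial interval 31.8 to 39.4, which takes the genes as independent). The genes were chosen on these same arrays, and quantile normalization moved the median of all genes only from -0.079 to -0.067. The part of scaling in the calls is therefore left undecided. Single calls did depend on the scaling: after median centring 17 passed, and the 23 others went from a median of -0.523 (SE 0.108) to -0.468 (SE 0.118) and from a median adjusted p of 0.0414 to 0.0761, with the parts of fold and SE in the loss not separated. RNA quality cannot be told apart from treatment here, since the same genes were higher in number 3 than in numbers 1 and 2 by 0.251 (0.189 to 0.433), between the bounds set for either answer. Of the 4 splits of the arrays that part all 3 pairs, 1, the real one, gave as many genes (40, highest other 0), too few splits for a share under 0.05. An effect of IFN-beta stays open as the biological explanation, and was not tested further.

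Oxidative phosphorylation genes were lower by a median of -0.16, but of -0.0286 without IFN-beta replicate 2, above the -0.0637 of all genes there. For the median of all 6 arrays, a shift that depends on signal level is left undecided. That median lay at percentile 0.08 among 10000 random lists of the same size matched on mean signal, whose medians centred on -0.0725. Those lists were drawn gene by gene, while this list's members had an estimated correlation of 0.237. The draws therefore spread too little, and the percentile is too extreme. RNA quality cannot be told apart, since the list was higher in number 3 by 0.172 (0.0572 to 0.28), an interval that neither reaches its fall throughout nor lies below 0. Nor can the weight of a single array, since the list lay below 0 in each pair (medians -0.0904, -0.23 and -0.101, against -0.0856, -0.0772 and -0.0532 for all genes), but without pair 2 it was below all genes by only -0.0331 (95% bootstrap interval -0.077 to 0.0328). An effect of IFN-beta stays open, and the adjusted p of 0.729 with an estimated correlation leaves the list short of a call.

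The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. For genes past the threshold 1 split, the real one, gave as many as 56, and the highest other gave 0. The other 3 splits that part all pairs had 9 to 23 genes at an unadjusted p under 0.05, and the 6 that keep 2 pairs together had 343 to 731, which points to the structure by replicate number. For lists past camera with the preset correlation, 1 split reached the real 11, but the highest other, which set untreated 1 and 3 and IFN-beta 3 against the rest, gave 10. With the estimated correlation the real split gave 6 lists and all 9 others gave 0. The preset-correlation p-values thus carry little weight on their own.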

How the results depend on the processing

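The combinations of the block with another choice, the omissions of a pair and the removal of single list members were chosen after seeing the data. Among the alternatives fixed beforehand without the block and with all 6 arrays, 54 to 59 genes rose (67 of 7615 when every probe set was tested on its own), and 0 fell, except 1 without the intensity trend and robust variances. With arrays left out, the count ran from 14, without both arrays of number 2, to 55, without IFN-beta replicate 3. It was 37 without IFN-beta replicate 2 or without both of number 1, and 29 without both of number 3. These omissions leave fewer arrays.

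The replicate block gave 171 genes higher and 40 lower. Combined with it, higher and lower were 163 and 26 without pair 1, 154 and 53 without pair 2, and 170 and 23 without pair 3. They were 168 and 37 at offset 0, 175 and 41 at 4 times the offset, 136 and 6 with no filter, and 161 and 43 with the stricter filter. They were 175 and 43 after quantile normalization, 196 and 17 after median centring, 155 and 27 for the mean of probe sets, 209 and 39 for every probe set, 156 and 34 without suffixed probe sets, and 125 and 7 without trend and robust variances. The number of genes that fell therefore depended on the filter, the centring and the variance model. The cause was not tested.

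Of the 28 named genes past the threshold, 27 stayed positive in every setting run and 9 stayed past it in all. With 1 array left out, 21 kept their call. H2-K1 reversed to -0.0704 without suffixed probe sets, with and without the block, because another of its probe sets was then used. Without Igf2bp1, the antiviral list had a camera adjusted p of 2.69e-57, and adjusted p = 0.00416 with an estimated correlation, and no list changed sides. Without the S6 kinases and assembly factors the ribosomal list had 0.379, and 0.00488 when blocked, but adjusted p = 0.244 with an estimated correlation. Oxidative phosphorylation had 0.0159, but adjusted p = 0.76 with an estimated correlation, and no list changed sides.

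For the lists, adjusted p with the estimated correlation was 0.132 for chemokines and cytokines, 0.125 for cell death, immediate early and heat shock, and 0.729 for oxidative phosphorylation. By fry these were 0.0831, 0.106, 0.314, 0.401 and 0.525. With the replicate block and the estimated correlation no list passed, at 0.197 for the antiviral, GTPase, MHC, signalling, pattern-recognition, ISGylation, chemokine, cell death and heat shock lists, 0.244 for immediate early and 0.41 for oxidative phosphorylation. The block leaves few degrees of freedom for this test, so a miss in it says little. With the replicate block and fry, 0.17 for immediate early and 0.148 for oxidative phosphorylation missed, while chemokines and cytokines (0.00769), cell death (0.0345) and heat shock (0.0364) passed upward. The cell cycle list and the muscle and neural list (both 0.0345) and ribosomal proteins (0.0146) passed downward, but with the block adjusted p = 0.362, 0.503 and 0.244 with an estimated correlation.

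Ribosomal proteins passed camera with the replicate block, at 0.00665, and with the block plus pair 1, 2 or 3 left out (0.026, 0.0105, 0.0232), offset 0 (0.00688), 4 times the offset (0.00587), no filter (0.0382), the stricter filter (0.00996), the mean of probe sets (0.0456) or no suffixed sets (0.0162). They did not pass with the block plus quantile normalization (0.711), median centring (0.113) or no trend and robust variances (0.16). Oxidative phosphorylation missed with no filter (0.0764) and with the block without pair 2 (0.0794). With arrays left out, camera's adjusted p ran from 0.032 to 0.806 for the cell cycle, 0.0168 to 0.933 for sterol synthesis, 0.00638 to 0.134 for heat shock, 0.023 to 0.976 for leukocyte markers, 0.0122 to 0.976 for ribosomal proteins and 0.00135 to 0.915 for oxidative phosphorylation. The cause was not tested. The group differences in the Actb and Gapdh 3'/5' ratios moved by less than the spread between arrays in all alternatives run. The block changed no other list's side of the threshold in camera with the preset correlation. Signals under the offset of 13.8, which held 16.3% to 22.1% of probe sets per array, limit how far the fold changes of genes such as Gbp2 and Usp18 can be read.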

Other observations

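The test of neighbouring genes below was chosen after the result was seen, and so were the genes named here. Of the 56 risen genes, 15 stood on none of the fixed lists. They included Mov10, an RNA helicase (signal 43.8 to 402, log2 fold change 2.98), the zinc-finger genes Trafd1 (155 to 1237, 2.89) and Znfx1 (75.4 to 623, 2.80), and Cmtr1, which methylates the cap of messenger RNA (219 to 722, 1.66). The galectin gene Lgals9 (128 to 642, 2.17) and Lgals3bp, whose product binds galectins (77.3 to 637, 2.86), also rose. So did Pnp and Nampt, enzymes of purine salvage and NAD synthesis, the former already bright in untreated cells (1890 to 5783, 1.60).

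In the blocked model 111 of 171 risers stood on no list. Among those past the threshold only there were Serpinb9, an inhibitor of granzyme B (293 to 1678, log2 fold change 2.34, blocked adjusted p 3.63e-04), Cd47, a surface signal that restrains phagocytosis (793 to 1656, 1.08, 0.00582), Ly6e (2180 to 4910, 1.17, 6.92e-04) and the coagulation initiator F3 (392 to 933, 1.22, 5.64e-04). Ccl2 signals were 48.6, 1060 and 412 in untreated arrays 1 to 3 and 340, 4031 and 2752 with IFN-beta, so each pair rose although the groups overlapped.

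Risen genes lay next to one another more often than random genes. Of the 56, 26 had another risen gene as an adjacent tested gene on GRCm38.p6, against a mean of 1.07 and a maximum of 8 in 10000 random draws. Much of this came from related genes such as Ifit1, Ifit2 and Ifit3, or Gbp2, Gbp3 and Gbp7. After leaving out neighbours that share their first 3 letters or are both on the GTPase list, 7 remained: Nampt and Gdap10, Psme1 and Irf9, and Tap1, Psmb8 and Tap2 (mean of draws 1.03, permutation p 0.002). Of these 7, Tap1, Psmb8 and Tap2 all stand on the MHC class I and antigen-processing list, so the permutation p does not show clustering beyond related genes. A hypothesis is that shared regulation of adjacent genes may add to the clustering, but 7 genes from 3 places are few, and transcripts that overlap or probes that cross-hybridise were not excluded.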
